A study of Homo sapiens with 12 samples.

How the data were processed

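RNA sequencing of H1299 cells with a control vector (shNT, 3 libraries) or a short hairpin against GAS41 (shGAS41, 3 libraries) was analysed from 1 deposited table. Per the labels' protocols, cells were infected with viral vectors and drug-selected before the experiments, mRNA was prepared with the RNeasy Plus kit, and libraries made with the TruSeq RNA kit were sequenced on an Illumina HiSeq. The submitters' processing notes name CASAVA 1.8.2, Bowtie2 2.1.0, TopHat2 2.0.10, MACS 1.4.2 and HTSeq for the series as a whole, and the build hg19, without saying which tool served which assay. The annotation release, the counting options, the use of strand and the way RNA was selected are not given in the sources used here. Without a statement on strand, reads of overlapping or antisense genes may be counted together, and near-identical gene copies may share reads.

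The deposited table holds raw whole-number counts per Ensembl gene and library, with totals that differ between libraries (58629147 to 72747010). It also holds the authors' own comparison, a log2 fold change of knockdown over control with a p-value and an adjusted p-value per gene, for which the deposited file's name points to edgeR but gives no version or model. The authors' adjusted p-values equal a Benjamini-Hochberg adjustment of the deposited p-values over the listed genes to within 0.00138. The table lists 13853 genes, and the rule by which the authors chose them is not given in the sources used here. Symbols were used as the deposited file pairs them with identifiers: 13508 of the 13853 identifiers matched the gene name table used here, 20 symbols had been turned into dates and 4 were duplicates, and none of these was named. Older symbols in the gene lists were matched through the same table. Coordinates are not printed, because the annotation at hand (GRCh38) differs from the authors' build. That annotation was used only for pseudogene status, neighbours of YEATS4 and genomic span.

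The groups came from the sample titles. The main test, fixed with the lists and the naming rule before the data were examined, was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) of knockdown against control on the counts, with TMM scaling, filterByExpr, robust dispersion and Benjamini-Hochberg adjustment at 0.05. The filter left out 7 genes and kept 13846. No replicate block was used, since the labels do not say that replicate numbers mark a shared day. CPM values are TMM-scaled and given as mean ± SD of 3 libraries. The SE of a log2 fold change is its size divided by the square root of the F statistic. Large depth makes counting error small for most genes, so the spread between libraries sets the precision.

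A set of 40 gene lists (958 entries, 779 of them tested) was fixed before the data were examined. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with fry and an estimated correlation beside it. Each list's median was also placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Genes named in the text were YEATS4, the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between the groups (symbols starting with LOC, MIR, SNOR, RNU or RN7 and pseudogenes with a P-number suffix skipped), and up to 2 rising and 2 falling members of smallest p in each list with at least 3 calls or a passed test. List members may also be named to say that they were not called. Genes outside that rule are identified as such where they appear. Some results are not reported here. The rule then gave 143 genes, and for all 143 the 3 knockdown values lay on one side of the 3 control values. The rule required this of the largest rises and falls, and choosing list members by smallest p favours it. It is therefore no separate check of these genes, and it held for 72.3% of all tested genes.

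The same code was tested on simulated counts for the comparison of shGAS41 with shNT, drawn from the means and library sizes of the 13846 genes with 200 of them changed. It recovered 46% of 50 genes changed 1.25-fold, 92% of those changed 1.5-fold, 98% of those changed 2-fold and all of those changed 4-fold. Of 13646 unchanged genes 11 were called, 6.15% of the calls. In the real comparison 68.1% of the genes were called, a far larger share than the 200 changed here, so these rates need not hold there. A simulated list of 40 genes shifted by 0.5 on the log2 scale was called, and 0 of 100 unshifted lists were. Each gene was drawn independently in that simulation, whereas the estimated correlation within the real lists reached 0.81. The simulated lists therefore do not measure how often a list of correlated genes is called without a shift.

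The alternatives planned before the data were examined were DESeq2 1.42.0, median-ratio size factors, scaling by library size alone, no filter on low counts, a filter of 1 CPM in 3 libraries, each library left out in turn, the replicate number as a block, thresholds of 0.01 and 0.1, a minimum absolute log2 fold change of 1, and other settings of the list test. The authors' deposited comparison, the removal of both libraries numbered 1, and edgeR's glmTreat against a fold change of 1.5 were added after the data were examined. The planned settings for files without counts did not apply. The 6 chromatin immunoprecipitation samples were not analysed here.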

Results

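H1299 is a human line of non-small cell lung cancer cells. In these cells GAS41, the protein encoded by YEATS4, was depleted with a short hairpin (shGAS41), and cells carrying a control vector (shNT) served as the reference. GAS41 is a chromatin reader whose YEATS domain binds acetylated histone H3, and it is a subunit of the SRCAP and TIP60/EP400 complexes, which place the histone variant H2A.Z into chromatin. The expression data were read counts per gene from 3 control and 3 knockdown libraries. The control libraries held 72747010, 61626051 and 58961101 counts over the listed genes, and the knockdown libraries held 64851389, 72516636 and 58629147. The 10 most abundant genes took between 5.23 and 6.02% of the counts of a library. Libraries of one group differed by more than sampling noise, with a chi-square per degree of freedom between 4.24 and 28.4, so no pair was a repeat of one library. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The 6 chromatin immunoprecipitation samples of the series, of GAS41, H2A.Z and histone H3 marks, were not analysed here.

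The targeted transcript was low in every knockdown library. YEATS4 (ENSG00000127337) had 3245, 2923 and 2820 counts in the control libraries and 108, 127 and 116 counts in the knockdown libraries. That was 46.3 ± 1.89 CPM (read counts relative to the TMM-scaled library total) in control cells and 1.81 ± 0.179 CPM after knockdown (mean ± SD, n = 3 each). The log2 fold change was −4.68 ± 0.09 (SE), with an adjusted p of 6.35e-10 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The counts therefore followed the labels in all 6 libraries. In the authors' deposited table the log2 fold change of YEATS4 was −4.43.

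**Figure D1:**
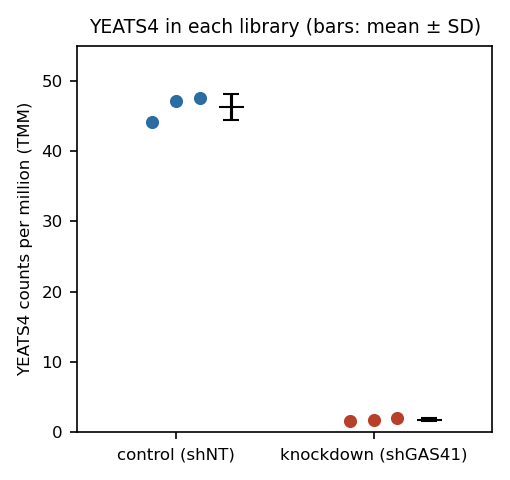
YEATS4 expression in CPM (TMM-scaled, y axis) in the 3 control and 3 knockdown libraries, each point being one library and each bar the mean ± SD of the group. The control libraries lie between 44.1 and 47.6 CPM and the knockdown libraries between 1.66 and 2.01 CPM.

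The comparison of knockdown with control cells asked which transcripts change when GAS41 is depleted. Transcripts of DNA replication, mitosis and recombination repair genes were lower after knockdown, with median log2 fold changes of −0.91, −0.73 and −0.93, and so were transcripts of ribosome biogenesis factors, with a median of −0.45. Transcripts of collagens, laminins, integrins, replication-dependent histones, and genes that respond to TGF-beta or NF-kB were higher, with list medians between 0.42 and 1.35. None of these list calls held with an estimated correlation (adjusted p from 0.0649 to 0.630 with an estimated correlation). Genes of the SRCAP and TIP60/EP400 complexes other than YEATS4 went both ways. The changes were widespread: of 13846 genes tested, 9425 (68.1%) changed at an adjusted p under 0.05, of which 4655 rose and 4770 fell. At this depth and spread (a biological coefficient of variation of 7.58% and a median SE of 0.08 on the log2 scale) small changes passed the test. With a minimum absolute log2 fold change of 1 in addition, 1399 genes remained, 886 rising and 513 falling. The knockdown and control values did not overlap for 72.3% of the genes, against 10% by chance in groups of 3.

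Among the more abundant genes the largest rise was that of BMF (ENSG00000104081), which encodes a pro-apoptotic BH3-only protein. It went from 1.85 ± 0.137 CPM in control cells to 26.1 ± 3.39 CPM after knockdown, a log2 fold change of 3.82 ± 0.12 (SE; adjusted p = 8.20e-09). Next came the secreted gelatinase MMP9 with a log2 fold change of 3.34, the locus CTD-2228K2.7 with 3.21, the secreted glycoprotein hormone STC1 with 3.13, and C15orf48 with 3.13. STC1 was the most abundant of these, at 42.6 ± 4.06 CPM in control and 374 ± 54.7 CPM in knockdown cells. The desmosomal protein gene PPL rose by 2.98, with a wide SE of 0.53. The matrix protein gene MATN2 (2.94), the metalloproteinase gene ADAM19 (2.78), the protease inhibitor gene SERPINA1 (2.71) and LGALS3BP (2.69), whose product is secreted, completed the 10 largest rises. After YEATS4, the largest falls were those of TRMT112, which encodes an activating subunit of several methyltransferases, and of MIEN1. TRMT112 (ENSG00000173113), at 144 ± 2.75 CPM in control cells, had a log2 fold change of −3.26 ± 0.06 (SE; adjusted p = 4.46e-10). MIEN1 went from 21.7 ± 1.41 to 2.27 ± 0.137 CPM, a log2 fold change of −3.26 as well. Then followed CCDC80 (−2.72), the zinc finger gene SALL3 (−2.66), the ubiquitin-conjugating enzyme gene UBE2C (−2.55), AATF (−2.54), the TFIIF subunit gene GTF2F2 (−2.53), the Polycomb gene CBX6 (−2.45) and the syndecan gene SDC1 (−2.40). The authors' deposited table called 9 of the 10 rises, and STC1 was not called there (log2 fold change 2.03, adjusted p = 0.0843). Of the 10 falls the authors' deposited table called 3, YEATS4, CCDC80 and SALL3, and it gave TRMT112 a log2 fold change of −0.60 (adjusted p = 0.315).

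Cell division genes fell together. All 46 measured DNA replication genes fell, by a median log2 fold change of −0.91, among them the thymidine kinase gene TK1 and the replicative helicase factor gene CDC45 (−1.38 ± 0.05, SE). TK1 went from 159 ± 7.25 to 56.3 ± 1.48 CPM (mean ± SD, n = 3). All 41 measured genes of mitosis and the G2/M transition fell as well, by a median of −0.73, including UBE2C and the anaphase-promoting complex activator gene CDC20 (−1.04 ± 0.04), which went from 508 ± 23.7 to 248 ± 2.94 CPM. In the list of homologous recombination and Fanconi repair genes 24 of 27 measured members fell and 1 rose, with a median of −0.93. BRCA1 (−1.40 ± 0.06) and XRCC3 (−1.38 ± 0.06) fell, while the damage kinase gene ATM rose by 0.30. In the list test (camera, preset correlation 0.01, adjusted over the 37 lists tested) the adjusted p was 4.32e-35 for DNA replication, 2.82e-24 for mitosis and 5.44e-15 for recombination repair. None of these calls held with an estimated correlation, where the adjusted p was 0.0703, 0.228 and 0.0649 in the same order.

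Regulators of entry into S phase showed a mixed picture with more falls than rises. Of 19 measured G1 cyclin, CDK and E2F genes 11 fell and 3 rose, with a median log2 fold change of −0.27 (list test adjusted p = 0.00777; adjusted p = 0.381 with an estimated correlation). The E2F transcription factor genes E2F8 (−1.70) and E2F1 (−1.36) fell, and MYC (0.34) and E2F3 (0.35) rose. Among 7 CDK inhibitor genes 4 rose and 1 fell, and the list did not pass its test (adjusted p = 0.637). CDKN2B, which encodes p15, rose by 1.84 ± 0.16 (SE) on the log2 scale, CDKN1B, which encodes p27, rose by 0.42, and CDKN3 fell by 0.78. Of 22 measured p53 target genes 11 rose and 5 fell, with a median of 0.21 (list test adjusted p = 0.0119; adjusted p = 0.213 with an estimated correlation). TP53INP1 (2.20 ± 0.07, SE) and the kinase gene PLK2 (1.24 ± 0.06) had the smallest p among the rises, and the nuclease gene AEN (−1.25) and the repair gene DDB2 (−0.68) among the falls.

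Ribosome biogenesis factors and ribosomal proteins moved in opposite directions. Of 33 measured ribosome biogenesis genes 29 fell and none rose, with a median log2 fold change of −0.45 (list test adjusted p = 2.05e-06; adjusted p = 0.630 with an estimated correlation). NAT10 (−0.77), an acetyltransferase that acts on 18S ribosomal RNA, and UTP20 (−1.22), a part of the small-subunit processome, were among them. Of 53 cytosolic ribosomal protein genes 43 rose and 1 fell, by a smaller median of 0.24 (list test adjusted p = 7.00e-05; adjusted p = 0.568 with an estimated correlation). RPL3 rose by 0.64 and RPL15 by 0.56. RPLP2 was the member that fell (−0.13, adjusted p = 0.0417). Its call was lost without control library 2 (adjusted p = 0.0972) or 3 (0.159), without knockdown library 1 (0.0623) or 2 (0.131), and in 11 of 18 alternatives.

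Matrix and adhesion genes rose. Of 20 measured collagen, laminin and matrix genes 16 rose and 3 fell, with a median log2 fold change of 1.35 (list test adjusted p = 2.70e-10; adjusted p = 0.0649 with an estimated correlation). The collagen VI genes COL6A2 and COL6A1 rose from 65.3 ± 2.53 to 218 ± 5.60 CPM and from 66.9 ± 3.05 to 209 ± 8.19 CPM (mean ± SD, n = 3), and THBS1 (−0.80) and COL12A1 (−0.58) fell. Of 24 integrin and focal adhesion genes 19 rose and none fell, with a median of 0.42 (list test adjusted p = 3.20e-07; adjusted p = 0.0649 with an estimated correlation). ITGB3 had a log2 fold change of 3.31 ± 0.12 (SE) and ITGA5, which encodes the alpha subunit of a fibronectin receptor, went from 64.3 ± 7.82 to 276 ± 12.3 CPM. Of 18 TGF-beta response genes 13 rose and 1 fell, with a median of 0.87 (list test adjusted p = 0.000121; adjusted p = 0.381 with an estimated correlation). The receptor gene TGFBR2 (1.45) and BHLHE40 (1.33) rose, while CTGF, which codes for a matrix-associated growth factor, fell by 0.60. Of 17 mesenchymal and EMT regulator genes 9 rose and 2 fell, with a median of 0.34 (list test adjusted p = 0.0423; adjusted p = 0.287 with an estimated correlation). LOXL2 (1.11) and SPARC (2.86) rose, and MMP14 (−0.68) and the transcription factor gene ZEB1 (−0.23) fell. This last list lost its call in the fit without control library 3 (adjusted p = 0.0593, within a range of 0.000711 to 0.287 over its camera alternatives, the estimated correlation included). Among 16 epithelial junction and keratin genes 8 rose and 6 fell (list test adjusted p = 0.698). Here CLDN4 (1.65) and CDS1 (2.49) rose from low levels, and the keratin genes KRT8 (−0.67) and KRT18 (−0.44) fell.

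Replication-dependent histone genes rose while the replication genes fell. Of 16 measured members 15 rose and 1 fell, with a median log2 fold change of 1.30 (list test adjusted p = 4.95e-10; adjusted p = 0.0649 with an estimated correlation). HIST1H2AC rose from 20.1 ± 0.325 to 72.8 ± 4.17 CPM, HIST1H2BD rose from 4.75 ± 0.735 to 29.8 ± 2.87 CPM, and HIST1H2BH fell by 0.97. Most transcripts of these genes are known to end without a poly(A) tail, and how RNA was selected for the libraries is not given in the sources used here. Their near-identical copies can also share reads. Among 26 genes of the SRCAP and TIP60/EP400 complexes and H2A.Z, 7 rose and 12 fell, YEATS4 included, and the list did not pass its test (adjusted p = 0.0754, and 0.507 with YEATS4 left out, the highest of its alternatives, which began at 0.00259). TRRAP (−0.97), a scaffold subunit of TIP60/EP400, had the smallest p among the falls after YEATS4, and MORF4L1 (0.82) and MBTD1 (0.81) had the smallest p among the rises. SRCAP itself had a log2 fold change of 0.04 and did not pass the test (adjusted p = 0.454). H2AFZ, an H2A.Z gene named here because H2A.Z is a subject of the series, lies outside the rule for named genes. It fell from 499 ± 13.3 to 341 ± 8.28 CPM (log2 fold change −0.55 ± 0.04, SE). This gene alone does not stand for H2A.Z expression as a whole. Among 19 H3 acetyltransferases and readers of acetylated H3, 6 rose and 9 fell (list test adjusted p = 0.698), with ZZZ3 (0.34) and BRD2 (0.30) higher and MLLT1 (−0.60) and DPF2 (−0.53) lower.

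NF-kB and interferon response genes were higher. Of 14 measured NF-kB feedback and TNF response genes 12 rose and 1 fell, with a median log2 fold change of 0.95 (list test adjusted p = 0.00187; adjusted p = 0.568 with an estimated correlation). BCL3 (1.08 ± 0.06, SE) and NFKBIA (1.14 ± 0.09), which codes for an inhibitor of NF-kB, rose, and SOD2 fell by 0.39. Of 14 type I interferon response genes 10 rose and 2 fell, with a median of 0.45 (list test adjusted p = 0.0423; adjusted p = 0.381 with an estimated correlation). IFIT2 rose from 1.97 ± 0.186 to 12.4 ± 2.53 CPM and IFIT3 from 3.43 ± 0.144 to 8.44 ± 0.436 CPM, while BST2 (−1.19) and OAS3 (−0.39) fell. The interferon call ended in the fits without control library 2 (adjusted p = 0.0533), without control library 3 (0.0547) and without knockdown library 1 (0.0517), within a range of 0.0169 to 0.381 over its camera alternatives, the estimated correlation included. Of 11 measured genes of the senescence-associated secretory phenotype 6 rose and 3 fell (list test adjusted p = 0.352, 0.0677 without knockdown library 1 and 0.0267 over members of 1 list only, within a range of 0.0267 to 0.886, the highest being the adjusted p with an estimated correlation), with PLAU (1.22) and CXCL2 (0.94) higher and IGFBP3 (−2.31) and VEGFA (−0.41) lower.

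Autophagy, lysosome and apoptosis genes rose more often than they fell. Of 31 autophagy and lysosome genes 14 rose and 5 fell, with a median log2 fold change of 0.12 (list test adjusted p = 0.0110; adjusted p = 0.381 with an estimated correlation). That median lay within the central 95% of random lists matched on mean expression (−0.23 to 0.16), at percentile 94.8. Of all 13846 tested genes 4655 rose and 4770 fell. SQSTM1, which encodes the autophagy receptor p62, rose from 345 ± 11.6 to 872 ± 20.2 CPM and the cathepsin gene CTSB from 156 ± 8.23 to 310 ± 4.28 CPM. The proton pump gene ATP6V1H (−0.56) and the lysosomal channel gene MCOLN1 (−0.43) fell. Of 22 apoptosis regulators 10 rose and 4 fell, and the list missed the threshold (adjusted p = 0.0594), but passed it without control library 2 (0.0385) or knockdown library 1 (0.0488). The range was 0.0385 to 0.297, the highest being the adjusted p with an estimated correlation. The BH3-only genes BMF and BCL2L11 (1.59) rose, and the pro-apoptotic genes BAD (−0.89) and BAK1 (−0.69) fell.

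**Figure D2:**
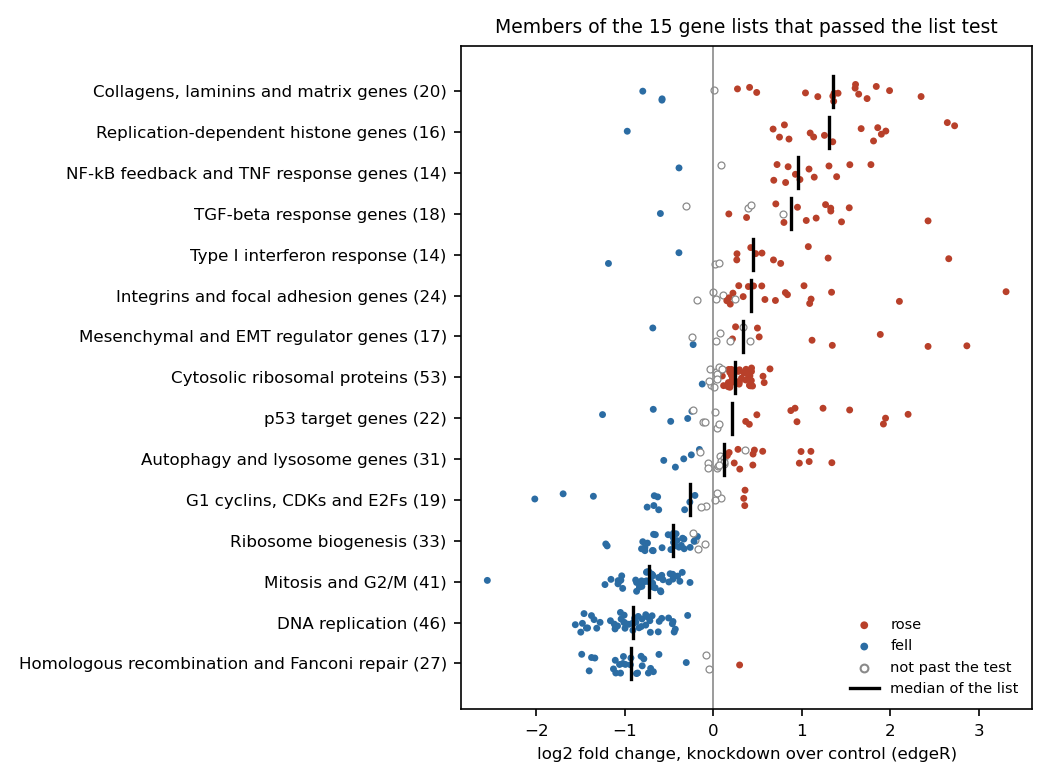
Log2 fold change of knockdown over control (edgeR, x axis) for each measured member of the 15 gene lists that passed the list test, with the number of members in parentheses. Red and blue points rose and fell at an adjusted p under 0.05, open points did not pass, black bars are list medians, and the vertical scatter within a row has no meaning. The 46 DNA replication genes all lie below 0, and 43 of the 53 cytosolic ribosomal protein genes rose by small amounts.

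Other lists of signalling, stress and metabolic genes held changes in both directions and did not pass the list test. Among YAP/TAZ targets 11 of 21 rose and 6 fell (adjusted p = 0.296), with NT5E (0.78) and PTPN14 (0.60) up and IGFBP3 and AMOTL1 (−0.76) down. Growth factor receptors and ligands had 11 rises and 4 falls among 20 (adjusted p = 0.138), with ROR1 (1.34) and DDR1 (1.18) up and NRG1 (−0.85) and FGF5 (−0.68) down. Notch and Wnt target genes had 10 rises and 4 falls among 17 (adjusted p = 0.252), with RNF43 (1.71) and TCF7 (0.79) up and NRARP (−0.54) and ZNRF3 (−0.48) down. The 22 immediate early genes had 8 rises and 6 falls (adjusted p = 0.698), with KLF4 (0.78) and FOSL1 (0.62) up and NR4A1 (−0.93) and DUSP6 (−0.31) down. Of 27 ATF4 and unfolded protein response genes 5 rose and 13 fell (adjusted p = 0.765), with DDIT4 (1.54) and DNAJB9 (1.47) up and SHMT2 (−0.47) and PDIA4 (−0.43) down. The heat shock list had 4 rises and 5 falls among 12 (adjusted p = 0.472), with SERPINH1 (0.46) and HSPA8 (0.20) up and DNAJA1 (−0.70) and HSP90AA1 (−0.45) down. NRF2 targets had 4 rises and 5 falls among 15 (adjusted p = 0.940), with NQO1 (0.36) and TKT (0.30) up and PGD (−0.58) down.

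In metabolism, hypoxia and glycolysis genes were split 9 to 9 among 25 (adjusted p = 0.698), with BNIP3L (1.06) and SLC16A3 (0.89) up and ADM (−0.94) and PFKL (−0.42) down. Sterol synthesis genes had 5 rises and 10 falls among 23 (adjusted p = 0.639), with INSIG1 (1.17) up and EBP (−0.62) and NSDHL (−0.45) down. Fatty acid synthesis genes had 2 rises and 4 falls among 13 (adjusted p = 0.666), with ELOVL6 (0.59) and ACSS2 (0.58) up and FADS2 (−2.39) and ELOVL5 (−0.38) down. Of 34 nuclear-encoded oxidative phosphorylation genes 17 fell and 1 rose, and the list missed the threshold (adjusted p = 0.0513), but passed it without knockdown library 3 (0.0360). The range was 0.0165 to 0.575, the highest being the adjusted p with an estimated correlation. UQCRFS1 (−0.92) and NDUFA9 (−0.58) fell, and NDUFB5 rose by 0.25.

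Few markers of other cell types were measured, and some of them changed. Of 18 immune cell markers 1 was measured, ITGAM, which rose from 5.71 ± 1.02 to 12.2 ± 1.91 CPM. Of 16 fibroblast and endothelial markers 2 were measured and both rose, COL1A1 (1.04) and ESAM (0.71), each from under 1 CPM. Of 5 measured lung epithelial lineage markers 2 fell and none rose (adjusted p = 0.505), SOX2 (−1.47) and MUC1 (−1.38). ITGAM, COL1A1, ESAM, SOX2 and MUC1 lie outside the naming rule and were chosen after their values were seen. Among 8 neuroendocrine and neuronal markers 4 rose and 2 fell (adjusted p = 0.940), with CHGB (1.01) and SNAP25 (0.80) up and DLL3 (−2.81) and SYP (−0.83) down. The 10 cancer-testis antigen genes had 3 rises and 3 falls (adjusted p = 0.940), with GAGE1 (0.37) and PRAME (0.35) up and MAGEA1 (−0.59) and MAGEA3 (−0.37) down, in families whose near-identical copies can share reads. For these last 3 lists the median and the mean differed in sign: 0.03 and −0.48 for lung, 0.25 and −0.13 for neuroendocrine, and 0.06 and −0.01 for cancer-testis genes. Of 13 genes that neighbour YEATS4 at 12q15, 4 rose and 5 fell (adjusted p = 0.887), with CPM, which codes for carboxypeptidase M, at 0.98, FRS2 at 0.66, NUP107 at −0.76 and CCT2 at −0.44. Of 15 housekeeping reference genes 5 rose and 5 fell (adjusted p = 0.940), with B2M (0.44) and RPLP0 (0.34) up and TUBA1B (−0.53) and TBP (−0.33) down. Mitochondrially encoded genes, a further list, were not analysed here.

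Over all 40 lists, 37 had enough members to test and 15 passed, 10 upward and 5 downward. With an estimated correlation none passed by camera, 7 had an unadjusted p under 0.05, and fry, which tests whether a list moves one way without comparing it with other genes, passed 26. When p-values were adjusted over the list alone, 32 of the 39 lists with measured members kept the counts given above. The exceptions, adjusted over the list alone, were CDK inhibitors with 4 rising and 2 falling, secretory phenotype genes with 6 and 4, oxidative phosphorylation with 1 and 16, and ribosome biogenesis with 0 and 30. Integrins then had 20 and 0, TGF-beta response genes 15 and 2, and autophagy genes 13 and 5.

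The share of genes called and the direction of the calls varied with expression. In the lowest quartile of mean expression 1952 of 3462 genes (56.4%) changed and 60.6% of those rose, while in the highest quartile 2577 of 3462 (74.4%) changed and 47.8% of those rose (95% Clopper-Pearson interval 45.9 to 49.8%, which treats genes as independent). The 2 middle quartiles had 67.8 and 73.6% of genes called, with 48.9 and 42.9% of the calls rising. The rising share in the highest quartile passed 50% without control library 2 (51.0%) or control library 3 (51.6%).

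The authors' deposited table holds a comparison of its own, and it differed from the fit to the deposited counts. The authors' deposited table listed 4599 of 13853 genes at an adjusted p under 0.05, 2581 rising and 2018 falling, against 9425 in the fit. Of the 4595 of these that were tested in the fit, 4403 were called in the same direction there, 2441 rising and 1962 falling, 192 were not called, and none was called in the opposite direction. Across genes the log2 fold changes of the fit and of the authors' deposited table had a correlation of 0.880 (genes are not independent replicates), and the deposited values had a median of 0.12 against −0.01 in the fit. Large falls differed most. Apart from YEATS4, 23 genes with a mean log2 CPM of at least 3 fell by a log2 fold change of 2 or more in the fit, with a median of −2.37, and the authors' deposited table gave the same genes a median of −0.58 and called 7. The 36 genes that rose by 2 or more had a median of 2.30 in the fit, and the authors' deposited table gave them 1.98 and called 35. The cell division lists fell there too: the authors' deposited table called 34 of 46 replication, 23 of 41 mitosis and 18 of 27 recombination repair genes as falling, and none as rising. Of the 53 cytosolic ribosomal protein genes, 43 of which rose in the fit, the authors' deposited table called 5 as rising. Their median log2 fold change was nevertheless 0.25 there and 0.24 in the fit, beside the deposited median of 0.12 over all genes. The list also passed the list test on the deposited values (adjusted p = 0.0448). Of the 143 genes named by the rule, 13 had the opposite sign in the authors' deposited table, none of them called there: VEGFA, SOD2, BST2, PTPN14, PDIA4, PFKL, ELOVL5, RPLP2, KRT8, KRT18, THBS1, NRG1 and NRARP.

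**Figure D3:**
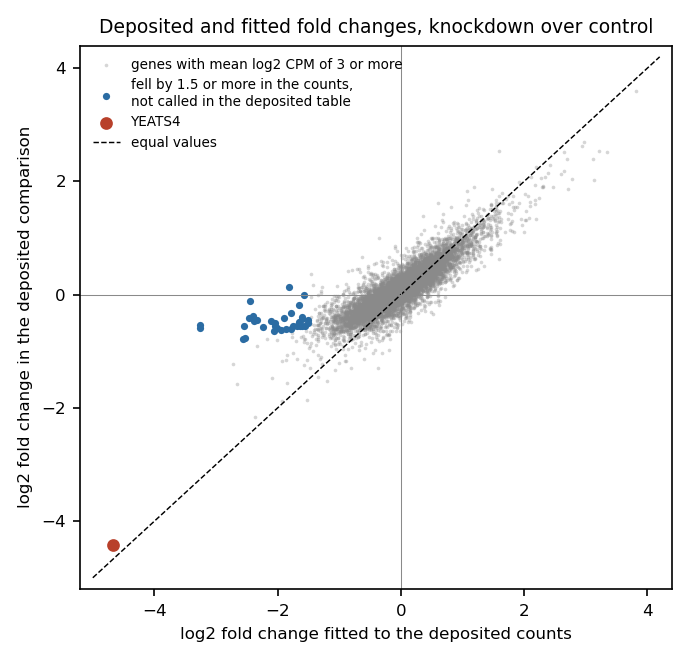
Log2 fold change of knockdown over control fitted to the deposited counts (x axis) against that in the authors' deposited table (y axis) for genes with a mean log2 CPM of at least 3, each point being one gene. Blue points are the 34 genes that fell by 1.5 or more in the fit and were not called in the authors' deposited table, the red point is YEATS4 (−4.68 and −4.43), and the dashed line marks equal values.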

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

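The authors' deposited comparison, glmTreat and the fit without both libraries numbered 1 were chosen after the data were seen. The call and direction of YEATS4 held under each alternative run, down to the authors' deposited log2 fold change of −4.43. For genes changed in shGAS41 against shNT, 9425 in number, the settings of scaling, filter, tool, block and threshold gave 7816 to 10394, and leaving out one library gave 8518 to 9377. The count moved to 2276 (1249 rising, 1027 falling) with glmTreat against a fold change of 1.5, to 1399 (886 and 513) with an absolute log2 fold change of at least 1, both by construction, and to 4595 (2577 and 2018) in the authors' deposited comparison. For the split of higher against lower calls by expression, the share of rising calls in the highest quartile, 47.8%, was 45.2% with library size alone, 44.1% with glmTreat, 53.4% with the minimum fold change, 44.2% in the authors' deposited comparison, and 45.5 to 51.6% with one library left out (51.0% without control library 2, 51.6% without control library 3), so it lay on both sides of an even split, and the cause was not tested.

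The replicate number as a block gave 10394 genes changed in shGAS41 against shNT, 5134 rising and 5260 falling, and 14 lists, the interferon list being lost (adjusted p = 0.0549). Same-numbered libraries had deviations from their group means with correlations of 0.446, 0.0783 and 0.0940 across genes. Only the libraries numbered 1 correlated best with each other, while those numbered 2 correlated best with those numbered 3. In each group the chi-square per degree of freedom was lowest between libraries 2 and 3. The libraries numbered 1 thus shared a deviation, whereas the numbers 2 and 3 did not pair the samples. The cause of that shared deviation was not tested. Without both libraries numbered 1, 9992 genes changed.

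With an estimated correlation 0 of the 15 lists stayed called by camera (7 lists had an unadjusted p under 0.05, and fry passed 26). A larger correlation was not the only reason. The estimates for p53 targets (−0.032) and EMT (−0.043) lay below the preset 0.01. Yet their unadjusted camera p rose from 0.00417 to 0.0345 and from 0.0171 to 0.0621. For integrins, with an estimate of 0.018, it rose from 5.18e-08 to 0.00702. The correlations were themselves estimated from these 6 libraries. Under the other 21 alternatives 9 lists kept their call: DNA replication, mitosis, recombination repair, ribosome biogenesis, NF-kB, matrix, integrins, TGF-beta and histones, with a highest adjusted p of 0.0164, that of NF-kB. The interferon list was lost under 8 (adjusted p from 0.0169 to 0.178, the highest over genes with a mean log2 CPM of at least 3) and EMT under 6 (0.000711 to 0.207, same setting). The p53 targets were lost under 2 (0.00318 to 0.126, ranks), autophagy under 2 (0.00782 to 0.188, fold change as statistic), G1 regulators under 1 (0.000998 to 0.0549, correlation of 0.05) and ribosomal proteins under 1 (3.74e-07 to 0.0989, fold change as statistic). Placing medians among random lists passed 12 of the 37 lists, matched on expression (10 of the 15, and YAP/TAZ and Notch and Wnt) or not (11 of the 15, and Notch and Wnt). The 26 that fry passed were the 15 and 11 others. Lists outside the 15 that passed in the 21 camera alternatives were apoptosis (3 settings), oxidative phosphorylation (4), and keratin, GAS41 complex, growth factor, Notch and Wnt, and secretory genes (1 each).

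Of the 143 named genes, 142 or 143 kept call and direction under each setting other than glmTreat (56 lost), the minimum fold change (80 lost) and the authors' deposited comparison (61 lost). The gene lost elsewhere was RPLP2, under DESeq2, median-ratio factors, the CPM filter, the threshold of 0.01, and without control library 2 or 3 or knockdown library 1 or 2 (highest adjusted p = 0.159, log2 fold change −0.07 without control library 3). The sign changed for 13 named genes in the authors' deposited table, none of them called there: VEGFA 0.042, SOD2 0.082, BST2 0.54, PTPN14 −0.086, PDIA4 0.07, PFKL 0.27, ELOVL5 0.16, RPLP2 0.002, KRT8 0.46, KRT18 0.15, THBS1 0.44, NRG1 0.10 and NRARP 0.19. In data simulated at this depth 46% of genes with the smallest fold tried and 92% of those changed 1.5-fold were recovered, and no other depth or share of changed genes was simulated.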

Other observations

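The tests of the mismatch between the deposited comparison and the counts, of the direction of genes missing from the former and of one library deciding their fall, and of scaling as the cause of the fall of division genes, were chosen after the results were seen; the other tests were written before their results were seen. Genes named from here on were chosen after their values were seen, unless the naming rule selects them. Several genes with very small p shared a theme that the fixed lists held only in part, and 3 further lists were written without the genes that had drawn attention. FOXO target genes other than BMF, TP53INP1, SESN3 and C10orf10 rose: 12 of 14 measured members rose and 1 fell, by a median log2 fold change of 0.42 (camera adjusted p = 0.00144 over the 3 lists; adjusted p = 0.0414 with an estimated correlation). FBXO32 (1.45), which codes for a muscle ubiquitin ligase, PIK3IP1 (1.61), an inhibitor of PI3 kinase, and BCL2L11 (1.59) led the rises, and SOD2 fell. Lysosomal hydrolase and membrane protein genes other than those that had drawn attention also rose, 24 of 32 with 3 falling and a median of 0.42 (adjusted p = 1.55e-07; adjusted p = 0.0246 with an estimated correlation). IDUA (2.28), MAN2B1 (1.20) and GAA (1.08), each a lysosomal hydrolase gene, were among them, and GLA (−0.61) fell. Mitochondrial ribosomal protein genes other than MRPL3 and MRPL11 fell, 47 of 64 with 2 rising and a median of −0.33 (adjusted p = 7.55e-06), but not with an estimated correlation (adjusted p = 0.169). The authors' deposited table called 10 FOXO target genes as rising and 0 as falling, 18 and 1 lysosomal genes, and 0 and 24 mitochondrial ribosomal genes, with a median log2 fold change of −0.16 for the last. The first 2 lists share 6 and 10 genes with fixed lists, among them BCL2L11 and CTSB, whose rises are given above. Adjusted p-values here are over 3 lists and those of the fixed lists over 37, so they cannot be set side by side. With an estimated correlation in camera, 7 fixed lists had an unadjusted p under 0.05, the smallest being 0.00511 for histone genes. As these lists were tested on the data that prompted them, a FOXO and lysosome response to GAS41 depletion and a fall of mitochondrial ribosome genes are hypotheses, and no technical explanation was tested for them. Measuring these lists in new libraries with a second hairpin and with GAS41 restored would test them.

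Counts of the XAGE1 family, whose members are near-identical copies, varied widely between libraries of one group: XAGE1E had 395 counts in knockdown library 3 and at most 11 in any other library, and XAGE1B had 147, 1630 and 856 counts in the control libraries.

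The deposited fold changes departed from the deposited counts. Over 6264 genes with a mean log2 CPM of at least 5 the difference between the deposited and the fitted log2 fold change had an SD of 0.255, against a median SE of 0.05, which argues against one scaling factor per library. A covariate fitted to the same 6 libraries is argued against by a regression of the deposited log2 fold change on the 6 log2 CPM values, whose residual SD was 0.175. In addition, 4 genes with at most 20 counts in each of the 6 libraries were called in the authors' deposited table at log2 fold changes of 7.38 (POSTN), 5.28 (FOXI1), 4.45 (BAMBI) and 3.32 (GPIHBP1). POSTN had 11 counts in all 6 libraries together. A candidate explanation is that libraries beyond these 6 entered the deposited comparison; no biological explanation was tested.

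A set of abundant genes fell in the counts and was not called in the authors' deposited table. Of 62 genes with a mean log2 CPM of at least 3 that fell by a log2 fold change of 1.5 or more, 34 were not called there, against 6 of 101 that rose as much, so that 85% of these discordant genes fell. TRMT112, MIEN1, AATF, CBX6, LSM7 (−2.33) and SGTA (−2.11) are among the 34. One deviating library is argued against, since at least 94.0% of the log2 fold change remained in each of the 34 whichever library was left out. Off-target silencing by the hairpin, which lowers transcripts, may account for such falls, but it cannot be told apart from true effects of GAS41 loss here: the hairpin sequence was not used here, and averaging with further libraries could hide falls more than rises. A second hairpin or a rescue would decide it for these genes.

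Replication, mitosis and recombination repair genes fell, although none of the 3 list calls held with an estimated correlation (adjusted p = 0.0703, 0.228 and 0.0649 with an estimated correlation). Of 114 genes in the 3 lists 111 fell and 1 rose, and the authors' deposited table called 75 of the 114 as falling. A scaling factor moves all genes of a library alike, but each list's median lay outside the central 95% of random lists matched on expression and genomic span by at least 0.498, which for each list was more than the width of that range and argues against scaling as the cause. Each median lay at percentile 0 of those random lists, whose central 95% reached from −0.23 to 0.21 over the 3 lists. That argues against a trend with expression level or genomic span. Transcript length was not matched, so a trend with it was not tested. The random lists take no account of correlation between genes. A lower expression of the division programme after GAS41 depletion is a hypothesis, slower growth after infection and selection or another effect of the hairpin was not tested, and a second hairpin and GAS41 restored, with growth measured alongside, would test it.

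The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The split by knockdown gave 9425 changed genes, as 1 of the 10 splits, and the highest of the others gave 1. Each of the others mixed knockdown and control libraries within its groups, which widens the spread there. Their low counts therefore do not measure what chance would give.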
